A study of Mus musculus with 6 samples.

How the data were processed

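Total RNA from small intestinal crypts of 6 libraries was measured by mRNA sequencing, with 50 bp single-end reads on a DNBSEQ instrument, per the labels' protocols. The submitters' processing notes name the mm10 build. The aligner, the counting tool and the gene annotation are not given in the sources used here. The values are estimated (expected) counts per gene as deposited by the authors, not normalised: between 31.1% and 35.2% of the values in a library are not whole numbers, and the totals differ between libraries. The design had assumed raw counts. Because the deposited values are estimated counts, they were rounded to whole numbers before the count tests. The kit's strand use is not stated, so reads of overlapping genes, and of near-identical copies such as the alpha-defensins, cannot be told apart with certainty.

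The table held 17526 genes with symbols and gene IDs, of which 17473 IDs were found in RefSeq for GRCm38.p6, the assembly that mm10 carries; coordinates are from that annotation. Total estimated counts ran from 11108511 to 16859902 per library, and did not separate the groups (exact two-sided permutation p = 0.2). Intervals on counts cover counting error only, since counts were pooled over the libraries of each group and the spread between libraries was left out. Reads carried no molecular identifiers. No pair of libraries was a duplicate. Genes of the formyl peptide receptor family, Fpr2 among them, and mitochondrially encoded genes were not analysed here.

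Differential expression used edgeR 4.0.16 in R 4.3.3: filterByExpr on group, which left 12943 genes, TMM scaling, glmQLFit with robust estimation, glmQLFTest for knockout over floxed control, and Benjamini-Hochberg adjusted p under 0.05. A size threshold of 2-fold was applied beside it. The biological coefficient of variation was 20.3%. CPM values are TMM-scaled, with SD over n = 3 libraries, and log2 fold changes carry SE. Fixed gene lists were tested with camera of limma 3.58.1 on edgeR log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over 34 lists. Beside it, members were counted that passed over all genes tested and adjusted over the list alone. A list's level in a library is the mean log2 CPM of its members, centred on the 6 libraries. Figures and exact tests used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

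The groups, tests, 41 gene lists, rule for named genes and processing choices to vary were chosen before the data were examined. The lists cover epithelial cell types, signalling programmes, stress, metabolism and other cell types, and were matched on exact symbols. A list needed 4 tested genes: the formyl peptide receptor and mitochondrially encoded lists had 0 genes here, and the fibroblast, erythroid and Brunner gland and stomach lists had 3 each and the pancreatic acinar list had 1. The sex-linked list was kept out of the test by design. Named genes were the anchors Lgr5, Olfm4, Ascl2, Mki67, Lyz1, Muc2, Chga, Dclk1 and Alpi, up to 4 members with the smallest p of each list described, genes with the 5 smallest adjusted p-values if called, and called genes with separated groups, an average log2 CPM of at least 1 and an established symbol. Where under 3 genes qualified in a direction, the 5 with the smallest p that met the other conditions were given as not passing. Xntrpc, Ddi2, Fam177a2, Fam177a, Wnt3, Ccl5, Clps, the globin genes, Vav1, Fyb and the clock genes fall outside that rule and were chosen after their values were seen.

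The tests were run on simulated counts for 12822 genes with the means and library sizes of these samples and 200 genes assigned a change. In that comparison of knockout and floxed control, 14.9% of genes changed 1.5-fold, 65.2% of those changed 2-fold and 95.3% of those changed 4-fold were called, as were 10 of 12625 unchanged genes. The simulated counts varied independently between genes. They held no difference shared by many genes, such as that between floxed control 2 and floxed controls 1 and 3. These shares may thus be too high for the real data, where Defa20, at log2 -2.12, was not called by edgeR (adjusted p = 0.0680). Alternatives were other scaling (DESeq2 size factors, and TMM without the 50 most abundant genes), DESeq2 1.42.0 and limma-voom, no filter beyond 1 count, a filter of 1 CPM in 3 libraries, replicate number as a block, each library left out, camera with an estimated correlation, fry, and lists without shared genes. Added after the data were seen were thinning to the smallest library, a split of the libraries on clock genes as a term or with its 2 libraries left out, and floxed controls 1 and 3 left out. DESeq2 gave no adjusted p for 251 genes, which were left as such.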

Results

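RNA was sequenced from mouse small intestinal crypts, the epithelial pockets that hold the stem cells, their dividing progeny and the Paneth cells. The 3 floxed control libraries came from mice carrying a floxed Fpr2 gene, and the 3 knockout libraries came from mice labelled VKO, read here from the study's title as a loss of Fpr2 from the intestinal epithelium. Fpr2 encodes formyl peptide receptor 2, a receptor for formylated peptides of bacterial and mitochondrial origin, and the comparison asks how its loss bears on stem cells, proliferation and differentiation in the crypt. Total estimated counts were 11108511, 16695304 and 12075398 in floxed controls 1, 2 and 3. In knockouts 1, 2 and 3 they were 16859902, 16542933 and 16827977. Of 17526 genes in the table, 12943 were tested. Fpr2 was not analysed here, so the genotypes could not be checked on the targeted gene. The labels do not say that the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

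Knockout crypts held less transcript of the Paneth cell, the granular cell at the crypt base that secretes antimicrobial peptides. The 24 genes of the Paneth cell list took 12.1% ± 3.78 of all counts in the floxed controls and 4.35% ± 0.897 in the knockouts (SD, n = 3 each, with exact two-sided permutation p = 0.1, the smallest that 3 libraries against 3 allow). The list holds only some of the 28 alpha-defensin genes, so these are not the shares of all Paneth cell genes. By camera with a preset correlation, the marker lists of goblet, enteroendocrine and tuft cells, of crypt base stem cells and of Wnt targets were lower as well, with medians between -0.999 and -0.33 on the log2 scale, and the S phase and G2/M lists were higher. None of these lists was called at an estimated correlation (adjusted p = 0.617 with an estimated correlation for each) or by fry. The equal value, here and below, comes from the adjustment over lists. Unadjusted, camera with an estimated correlation gave p from 0.0495 for the Paneth list to 0.290 for S phase. Estimated correlations ran from 0.297 for stem cells to 0.784 for tuft cells, far above the preset 0.01 on which the small camera p-values rest. Without floxed controls 1 and 3 the tuft and G2/M medians shrank to -0.22 and 0.10, and the S phase median turned to -0.034. That setting, here and below, leaves 1 control library, so the spread of the controls is not measured in it. By edgeR only 2 single genes, Trpc2 and Defa35, passed over all genes tested.

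The Paneth cell list had 24 tested genes, all with a negative log2 fold change, and a median of -1.69. By edgeR's quasi-likelihood test 23 of them fell, adjusted over the list alone, while 0 passed over all genes tested. In the list 23 had an unadjusted p under 0.05, and DESeq2 called 23 over all genes. The list was lower by camera with a preset correlation (adjusted p = 7.96e-26). That call was lost by camera with an estimated correlation, which was 0.770 (p = 0.0495 unadjusted, adjusted p = 0.617). The lowest adjusted p among the list's alternatives was 1.47e-34, by camera at the preset correlation without floxed control 3. Lowest values of this kind, here and below, were picked from many settings and rest on the preset correlation, so they add no support. Lyz1 (gene 17110), the lysozyme of Paneth cell granules, fell from 38310 ± 15900 to 11540 ± 3530 normalised counts (CPM, scaled by library size; SD, n = 3), a log2 change of -1.73 ± 0.41 (SE; adjusted p = 0.131 over all genes and 0.00169 over the list alone). Defa20, an alpha-defensin (antimicrobial peptide), had the largest fall of the list, from 6045 ± 2410 to 1390 ± 293 CPM (log2 -2.12 ± 0.34). Reads of the near-identical alpha-defensin copies could be shared among them, so the value of any single copy is uncertain. The 28 alpha-defensin genes together took 13.9% ± 4.64 of counts in the floxed controls and 4.90% ± 0.695 in the knockouts (exact two-sided permutation p = 0.1). Paneth genes outside that family fell too, among them Habp2, a hyaluronan-binding serine protease (log2 -1.41 ± 0.23), and Pnliprp2, a pancreatic lipase-related protein (log2 -1.84 ± 0.31). Mmp7, the metalloproteinase that activates mouse alpha-defensins, fell (log2 -1.42 ± 0.28). Clps, the colipase gene, was lower alongside them (735 ± 364 against 194.9 ± 44.1 CPM, log2 -1.91 ± 0.33). Its adjusted p over all genes was 0.0680 by edgeR and 2.07e-07 by DESeq2. Clps was fixed in the pancreatic acinar list, where it alone of 3 genes in the table was high enough to test. Its centred log2 level was highest in floxed control 3 and lowest in knockout 2, as for the Paneth list, and a pancreatic source was not tested. The lowest floxed control lay above the highest knockout for the share of counts in the genes of the Paneth list, at 9.20% against 5.36%. Without floxed controls 1 and 3, which stood apart on lymphocyte markers, the list's median was -1.20, against 1 control library. Clock genes set floxed control 2 and knockout 1 apart from the other 4 libraries; the list differed by -0.94 on the log2 scale within that pair and by -1.85 within the other 4.

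**Figure D1:**
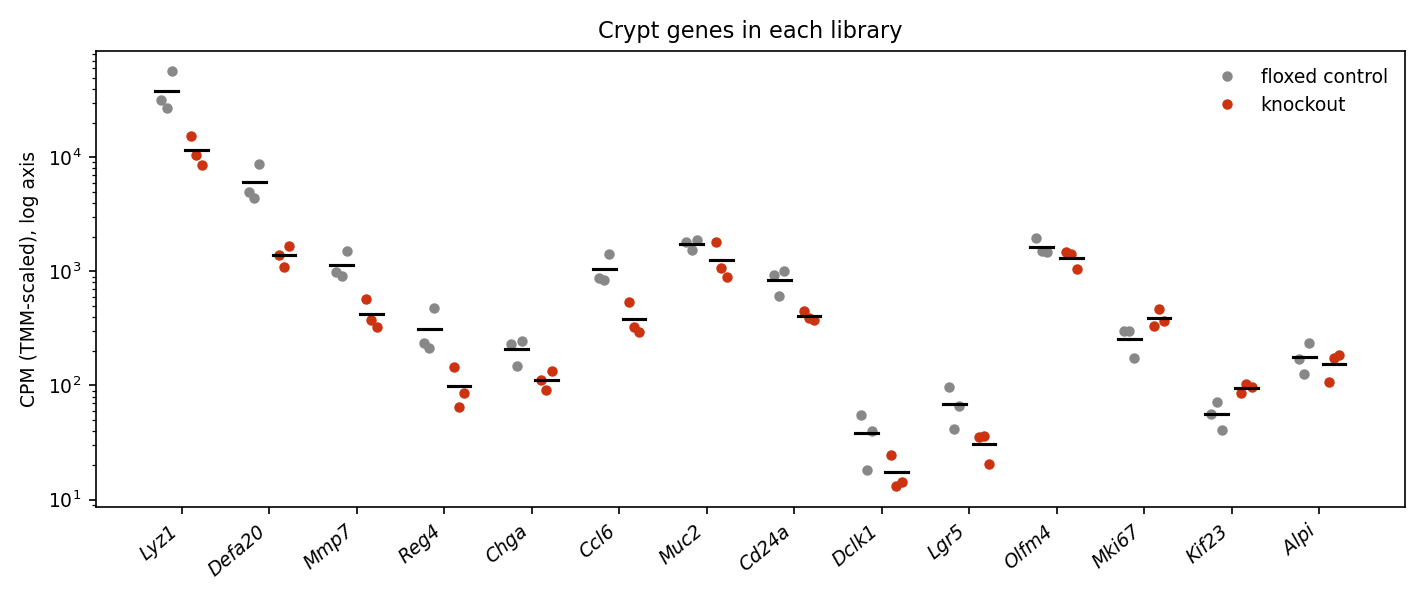
Normalised expression (CPM on a log axis) of 14 crypt genes in each of the 6 libraries, with points for single libraries and bars for group means. Lyz1, Defa20, Mmp7 and Reg4 were lower in each knockout library than in each floxed control, whereas the groups overlapped for Muc2, Dclk1 and Alpi.

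Of the goblet cell list, the genes of mucus-secreting cells, 18 of 24 tested genes fell adjusted over the list alone and 0 passed over all genes by edgeR. Of the 24 genes, 20 had an unadjusted p under 0.05 and DESeq2 called 11. The median was -0.85 (camera adjusted p = 9.25e-14). The goblet list had adjusted p = 0.617 with an estimated correlation and a lowest adjusted p of 3.35e-15 among the alternatives, without knockout 1. The chemokine genes Ccl6 and Ccl9 fell (log2 -1.44 ± 0.29 and -1.28 ± 0.23). Foxa3, a transcription factor of the secretory lineage, fell (log2 -1.03 ± 0.21), and Rep15 fell from 34.4 ± 2.89 to 17.2 ± 3.21 CPM. Muc2, the main secreted mucin, did not pass (1740 ± 166 against 1252 ± 488 CPM; log2 -0.48 ± 0.28, adjusted p = 0.495 by edgeR); its log2 change ran from -0.83 without knockout 1 to -0.27 without knockout 3. The list's median was -0.56 without floxed control 3, where it was called. It was -0.50 without floxed controls 1 and 3, against 1 control library.

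Enteroendocrine genes, from the hormone-secreting cells, were negative for each of 29 tested members, and 21 fell adjusted over the list alone. Over all genes 0 passed by edgeR, 23 had an unadjusted p under 0.05 and DESeq2 called 5. The median was -0.82 (camera adjusted p = 2.01e-15). Enteroendocrine genes had adjusted p = 0.617 with an estimated correlation and a lowest adjusted p of 5.66e-18 among the alternatives, without knockout 3. Reg4, a secreted lectin of enteroendocrine and deep secretory cells, fell (log2 -1.65 ± 0.35), and Gcg, the precursor of glucagon-like peptides, fell from 164.4 ± 38 to 89.8 ± 12.1 CPM. The endocrine transcription factors Insm1 and Fev fell (log2 -0.93 ± 0.21 and -1.08 ± 0.26). Chga, the granule protein chromogranin A, fell (log2 -0.89 ± 0.22) within the list, with an adjusted p of 0.140 over all genes. The list's median was -0.35 without floxed controls 1 and 3.

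Tuft cell genes, from the chemosensory cells, had a median of -0.999 over 23 tested members, of which 18 fell adjusted over the list alone. Over all genes 0 passed by edgeR, 19 had an unadjusted p under 0.05 and DESeq2 called 12. The list was lower by camera (adjusted p = 3.53e-11). As a list they had adjusted p = 0.617 with an estimated correlation and a lowest adjusted p of 5.43e-15 among the alternatives, with a replicate block. Pou2f3, the transcription factor that specifies tuft cells, fell (log2 -1.13 ± 0.28), as did Dclk1 (log2 -1.13 ± 0.37). So did Plcb2 of taste signal transduction (log2 -1.08 ± 0.27), Alox5ap of leukotriene synthesis (log2 -1.04 ± 0.24) and Cd24a (log2 -1.06 ± 0.23). Dclk1 overlapped between the groups, with floxed control 2 at 18.3 CPM and knockout 1 at 24.6 CPM. Its log2 change ran from -1.47 to -0.73 with single libraries left out. The members Vav1 and Fyb are also expressed by blood cells, whose markers were high in floxed controls 1 and 3. Without those 2 libraries the median was -0.22 and the list was not called.

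Crypt base stem cell genes had a median of -0.33 over 25 tested members, 22 of them negative. Of these, 4 fell adjusted over the list alone and 0 over all genes by edgeR; 11 had an unadjusted p under 0.05 and DESeq2 called 3. The camera adjusted p was 1.03e-05. Stem cell genes had adjusted p = 0.617 with an estimated correlation and a lowest adjusted p of 2.88e-07 among the alternatives, without floxed control 3. Lgr5 (gene 14160), the receptor that marks cycling crypt stem cells, fell from 68.6 ± 28.1 to 30.5 ± 8.88 CPM (log2 -1.17 ± 0.31; adjusted p = 0.153 over all genes and 0.0239 over the list alone). Sp5, Ephb3 and Tnfrsf19 fell (log2 -0.93 ± 0.18, -0.86 ± 0.21 and -0.91 ± 0.25). All members that fell over the list alone, Lgr5 included, are also in the Wnt target list. Without genes of more than 1 list the stem cell median was -0.23 (camera adjusted p = 0.0393 at the preset correlation). Olfm4 (log2 -0.33 ± 0.24, adjusted p = 0.596) and Ascl2 (log2 -0.44 ± 0.16, adjusted p = 0.273), further stem cell markers, did not pass over all genes or within this list. Olfm4 stood at -0.15 without floxed control 1 and -0.18 without knockout 3. Ascl2 fell when adjusted over the list alone of Wnt targets. The list's median was -0.18 without knockout 3, where it was called. It was -0.20 without floxed controls 1 and 3, against 1 control library.

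Wnt targets, genes switched on by the signal that maintains the crypt base, fell in 14 of 21 tested members adjusted over the list alone. Over all genes 0 passed by edgeR, 15 had an unadjusted p under 0.05 and DESeq2 called 6. The 7 members that did not pass within the list included several known targets. Axin2, Rnf43, Ephb2 and Cd44 had log2 changes of -0.26 ± 0.20, -0.11 ± 0.15, -0.049 ± 0.20 and -0.0084 ± 0.22. Myc and Ccnd1 had 0.053 ± 0.19 and 0.065 ± 0.19, and Lef1 had -1.05 ± 0.45. The median was -0.86 (camera adjusted p = 1.40e-09). Wnt targets had adjusted p = 0.617 with an estimated correlation and a lowest adjusted p of 1.84e-11 among the alternatives, without floxed control 3. Bambi, a BMP and activin pseudoreceptor, fell (log2 -1.56 ± 0.25), as did Nkd1, a feedback inhibitor of Wnt signalling (log2 -1.79 ± 0.37). The list is not independent of those above: 10 of its 21 tested members, Sp5 and Lgr5 among them, are also in the stem cell list, and Mmp7 is in the Paneth list. Wnt3, a ligand that Paneth cells supply to stem cells, is in the Paneth list and fell from 42.2 ± 8.83 to 16.4 ± 6.06 CPM. The median of the Wnt targets was -0.26 without floxed controls 1 and 3, against 1 control library.

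Notch pathway genes had a median of -0.31 over 15 tested members, 10 of them negative and 5 positive. Among the positive ones were the Notch target Hes1 (log2 0.37 ± 0.20) and the ligand Jag1 (log2 0.25 ± 0.23). Adjusted over the list alone, 5 fell. Over all genes 0 passed by edgeR, 6 had an unadjusted p under 0.05 and DESeq2 called 4. Heyl, a Notch target of low level, fell (log2 -2.37 ± 0.52). The Notch regulators Dtx1 and Lfng fell (log2 -1.54 ± 0.37 and -0.82 ± 0.20). Atoh1, the transcription factor that starts secretory differentiation, fell from 100.1 ± 17.2 to 55.2 ± 14.2 CPM. The camera adjusted p was 0.0256. The Notch list had adjusted p = 0.617 with an estimated correlation and a lowest adjusted p of 0.00781 among the alternatives, without knockout 2. The call was lost without floxed control 1 (median -0.15), without knockout 3 (median -0.10) and without floxed controls 1 and 3 (median -0.13).

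**Figure D2:**
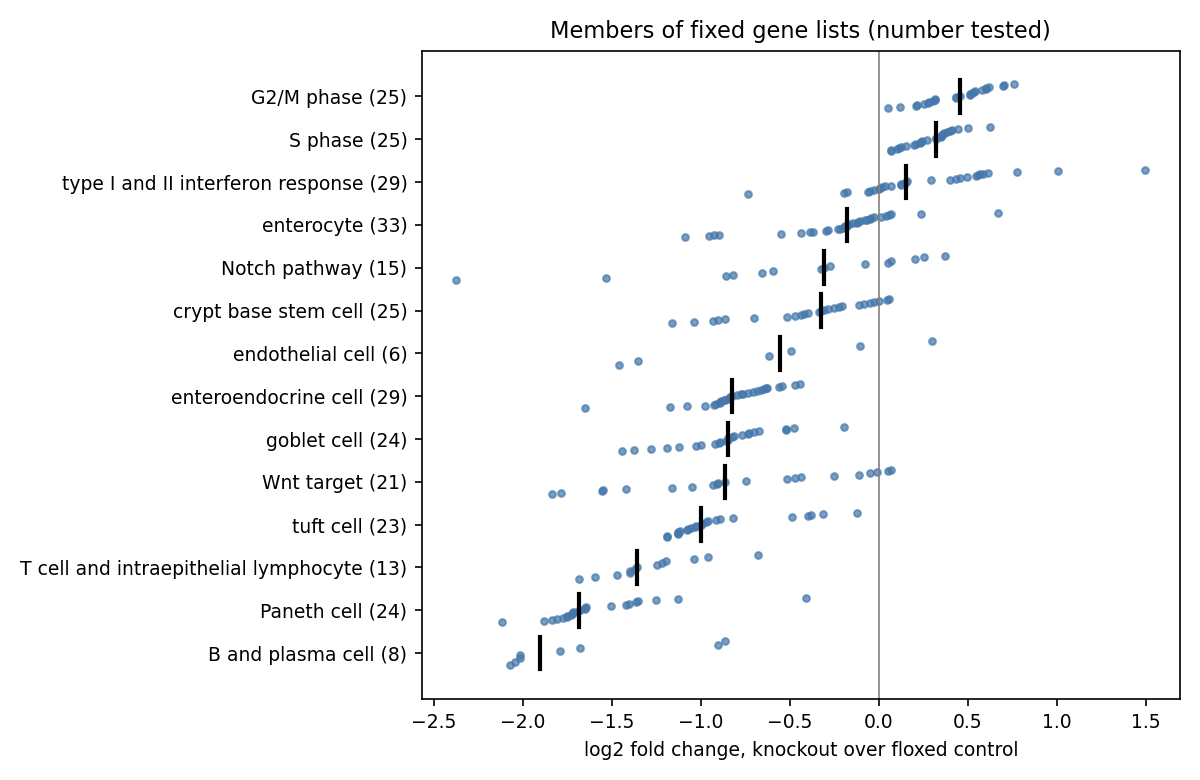
Log2 fold change (knockout over floxed control) of each tested member of the 13 lists called by camera and of the enterocyte list, with the number tested in parentheses and a black bar at the median. Each Paneth, goblet, enteroendocrine and tuft member lies below 0, and each S phase and G2/M member above it.

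The cell division lists were higher by camera with the preset correlation, although no single gene of them passed by edgeR. Each of the 25 G2/M genes and each of the 25 S phase genes had a positive log2 fold change, with medians of 0.45 and 0.32. Adjusted over the list alone, 0 G2/M genes passed by edgeR, as over all genes, with 11 at an unadjusted p under 0.05 and 2 called by DESeq2. Of the S phase genes 0 passed either way, 1 had an unadjusted p under 0.05 and DESeq2 called 0. Camera gave adjusted p = 2.89e-09 for G2/M and 1.23e-05 for S phase. Each had adjusted p = 0.617 with an estimated correlation. The lowest adjusted p among their alternatives, 4.8e-13 for G2/M and 5.15e-10 for S phase, came without floxed control 2. Kif23 and Bub1, which act in cytokinesis and at the spindle checkpoint, had log2 changes of 0.76 ± 0.20 and 0.70 ± 0.19 (adjusted p = 0.0503 over the list alone for each). Tpx2 and Hmmr of the spindle had 0.58 ± 0.19 and 0.51 ± 0.18. Mki67, the proliferation marker, had 0.60 ± 0.24 (256.5 ± 72.7 against 389 ± 71.5 CPM; adjusted p = 0.307), and Rrm2, of deoxynucleotide synthesis, 0.62 ± 0.22. The difference rested on floxed controls 1 and 3: floxed control 2 stood at 0.21 for G2/M, as centred log2 level, against 0.17, 0.29 and 0.26 in the knockouts. Without floxed control 2 the medians were 0.72 for G2/M and 0.55 for S phase, and without floxed controls 1 and 3 they were 0.10 and -0.034, with neither list called.

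Lymphocyte transcripts were high in floxed controls 1 and 3, while floxed control 2 lay below each knockout on both lymphocyte lists. Of the T cell and intraepithelial lymphocyte list, 11 of 13 tested genes fell adjusted over the list alone (0 over all genes by edgeR; 11 at an unadjusted p under 0.05; 5 called by DESeq2). The median was -1.36, with a camera adjusted p of 1.12e-05. The T cell list had adjusted p = 0.617 with an estimated correlation. Its lowest adjusted p among the alternatives, 1.27e-13, came without floxed control 2, the control that lay below the knockouts. Of the B and plasma cell list, 7 of 8 fell adjusted over the list alone (0 over all genes by edgeR; 7 at an unadjusted p under 0.05; 2 called by DESeq2). Their median was -1.90, with a camera adjusted p of 0.00162. The B cell list had adjusted p = 0.617 with an estimated correlation. Its lowest adjusted p among the alternatives, 1.12e-09, came without floxed control 2 and knockout 1. Gzma, a granzyme of cytotoxic lymphocytes, stood at 85.4, 25.2 and 68.5 CPM in floxed controls 1, 2 and 3 and at 18.6, 22.7 and 26.4 CPM in knockouts 1, 2 and 3. Jchain, the joining chain of secreted antibodies, stood at 21.2, 5.84 and 11.7 CPM against 5.87, 4.29 and 1.85 CPM. Without floxed controls 1 and 3 the medians were 0.18 and 0.19 and neither list was called. The B cell call was also lost without floxed control 1 alone, at a median of -1.24. Of the erythroid list, too short for the list test, the 3 globin genes Hba-a1, Hba-a2 and Hbb-bs fell adjusted over the list alone (log2 -1.94 ± 0.56, -2.85 ± 0.84 and -1.79 ± 0.53; adjusted p = 0.00672 for each). Over all genes 0 passed by edgeR, and DESeq2 called 2. Their centred log2 level was 1.40, -0.063 and 1.74 in floxed controls 1, 2 and 3 and -1.16, -1.58 and -0.34 in knockouts 1, 2 and 3, so here floxed control 2 lay above each knockout. The endothelial list, led by Prox1 (log2 -1.46 ± 0.39; also a gene of enteroendocrine cells) and Pecam1 (log2 -1.35 ± 0.45), had a median of -0.56 over 6 genes. Of these, 2 fell adjusted over the list alone (0 over all genes by edgeR; 3 at an unadjusted p under 0.05; 1 called by DESeq2). Its camera adjusted p was 0.0256. The endothelial list had adjusted p = 0.617 with an estimated correlation and a lowest adjusted p of 0.00629 among the alternatives, with no filter on low counts. Its call was lost without floxed control 1 (median -0.49) or knockout 3 (median -0.46), and without floxed controls 1 and 3 (median -0.36).

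**Figure D3:**
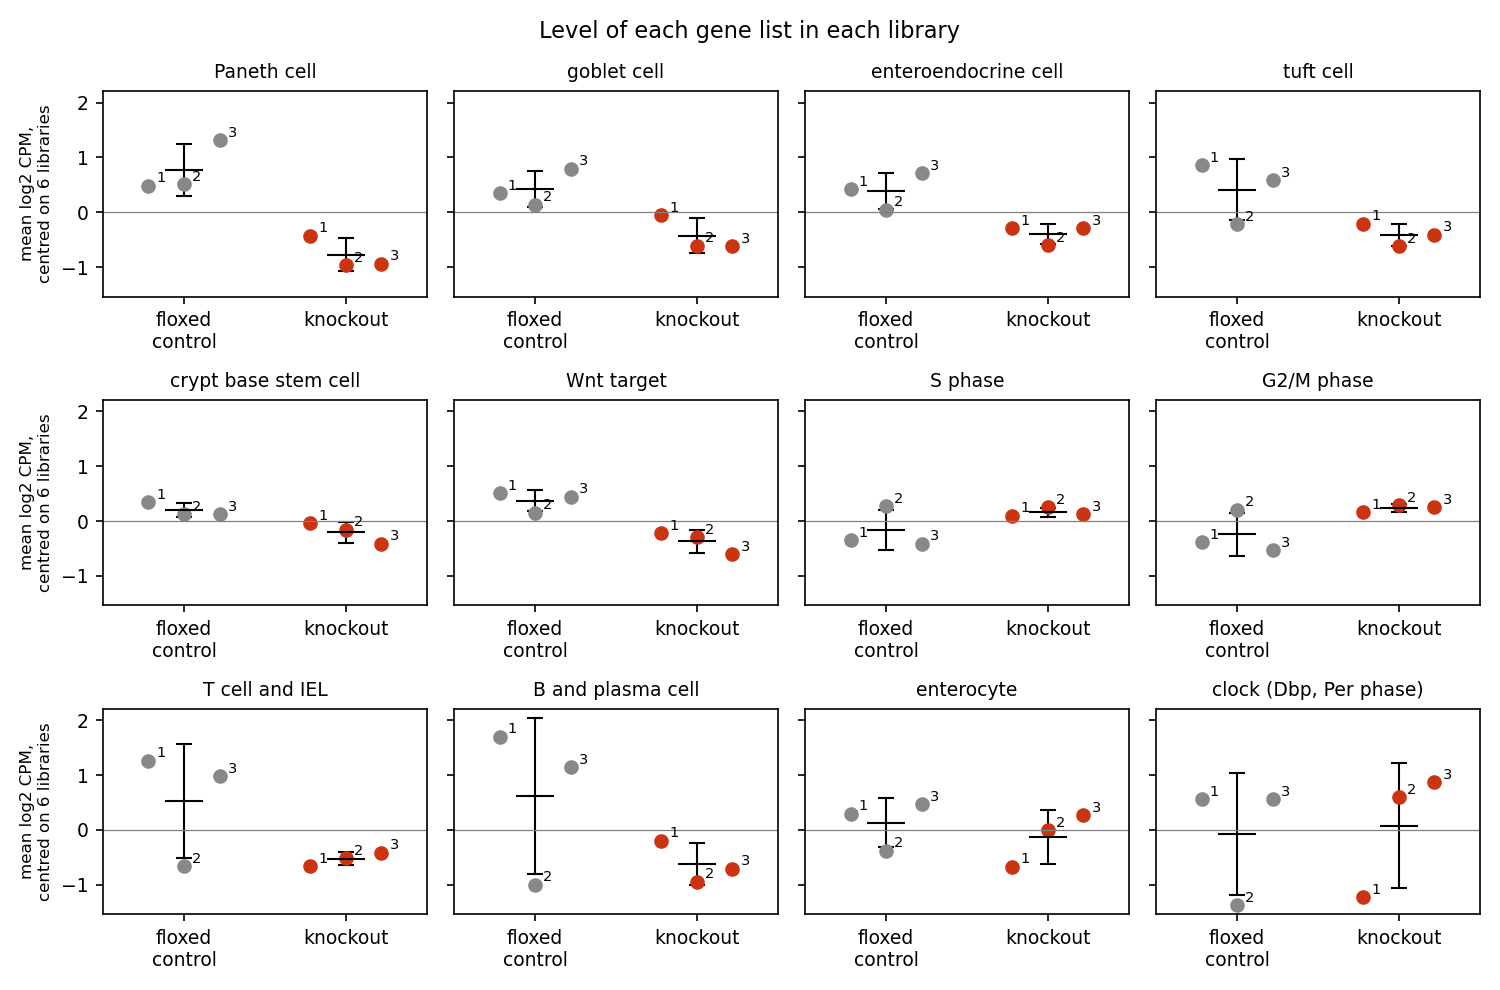
Mean log2 CPM of 12 gene lists in each library, centred on the 6 libraries, with the library number beside each point and group means with SD. The groups separate for the Paneth, goblet, enteroendocrine, stem cell and Wnt lists, while floxed control 2 lies with the knockouts on the tuft, T cell, B cell, S phase and G2/M lists; the last panel, of clock genes, sets floxed control 2 and knockout 1 apart from the other 4 libraries.

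Interferon response genes were higher as a list, with a median of 0.15 over 29 tested genes (camera adjusted p = 0.00616). The interferon list had adjusted p = 0.710 with an estimated correlation and a lowest adjusted p of 2.57e-11 among the alternatives, without knockout 3. None passed adjusted over the list alone or over all genes by edgeR; 3 had an unadjusted p under 0.05, and DESeq2 called 0. Ifi44 had a log2 change of 1.497 ± 0.43 (1.30 ± 0.396 against 3.70 ± 1.6 CPM), and the antiviral enzyme genes Oas2 and Oasl2 had 1.01 ± 0.40 and 0.61 ± 0.25. Leaving out 1 library moved Oas2 between 0.79 and 1.55 and Oasl2 between 0.34 and 0.86. The list's centred log2 level was 0.29 and 0.46 in knockouts 1 and 2 but -0.37 in knockout 3. The call was lost without floxed control 2 (median 0.17), knockout 1 (0.13) or knockout 2 (0.051). The list was called with a median of 0.50 without knockout 3 and 0.33 without floxed control 3. Its median was 0.61 without floxed controls 1 and 3, against 1 control library.

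On the absorptive side of the crypt the enterocyte list was not called: 33 tested enterocyte genes had a median of -0.18 (camera adjusted p = 0.0694). Of these genes 27 were negative and 6 positive, so a small fall is not excluded. Among them 1, Slc2a5, the fructose transporter, fell adjusted over the list alone (log2 -0.93 ± 0.22; 64.4 ± 19.4 against 33.8 ± 3.5 CPM). Over all genes 0 enterocyte genes passed by edgeR, 3 had an unadjusted p under 0.05 and DESeq2 called 2. The proximal small intestine list was not called by camera either, with a median of -0.21 over 14 tested genes, 10 negative and 4 positive. Adjusted over the list alone, 3 of its genes fell, and 0 passed over all genes by edgeR. These were Cybrd1, Slc5a4b and Slc5a4a (log2 -1.94 ± 0.39, -1.45 ± 0.39 and -1.05 ± 0.31). Alpi, the brush border alkaline phosphatase, stood at 177.5 ± 54.7 and 155.5 ± 42.9 CPM (log2 -0.19 ± 0.26, adjusted p = 0.810). The enterocyte median ranged from -0.36 without floxed control 2 or knockout 3, where the list was called lower, to 0.051 without floxed control 3. It was also called lower without knockout 2, at -0.20, and with the clock-gene split as a term, at -0.18. Antimicrobial and acute inflammatory genes had a median of 0.15 over 12 genes and were not called (camera adjusted p = 0.559). Of these, Retnlb had a log2 change of -1.37 ± 0.67, and Duoxa2, Lcn2 and Il18 had 0.32 ± 0.26, 0.40 ± 0.47 and 0.27 ± 0.31. Leaving out 1 library moved Retnlb between -2.14 and -0.85 and Lcn2 between 0.062 and 0.70. With single libraries left out the list's median ran from 0.024 without knockout 1 to 0.25 without knockout 2. Duoxa2 ran from 0.16 without floxed control 1 to 0.74 without floxed control 2, where it passed, and turned to -0.18 without floxed controls 1 and 3. The 21 lists not called had camera adjusted p-values from 0.0690 to 0.981, and for 4 of the 34 lists tested the median and the camera test differed in sign.

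Over all genes tested, edgeR's quasi-likelihood test called 1 gene higher and 1 lower in the knockouts at an adjusted p under 0.05, each with a change of more than 2-fold. Defa35 (gene 100041688; chromosome 8, 21065038 to 21066001, mm10), an alpha-defensin, fell from 78.8 ± 23.3 to 23.5 ± 1.97 CPM (log2 -1.75 ± 0.21, adjusted p = 0.0382), and it was lower in each knockout than in each floxed control. Trpc2 (gene 22064; chromosome 7, 102083116 to 102096864), a cation channel gene of the vomeronasal organ, had 2 counts in all floxed controls together and 191 in the knockouts, a ratio of 64.9 (95% exact interval 17.7 to 540, covering counting error only; log2 5.80 ± 0.68, adjusted p = 0.0382). The control counts were all in floxed control 3, and with single libraries left out the fitted log2 change ran from 5.13 to 8.85, the latter without that library and thus against 0 counts, where it is no bound. Trpc2 lies within the span of Xntrpc, a read-through gene whose own level was 3.02 ± 0.597 CPM in the floxed controls and 0.251 ± 0.435 CPM in the knockouts, so the counts of either gene are uncertain. Both calls were lost without floxed control 3, knockout 1 or knockout 3, under both other scalings and with the clock-gene split as a term, and that of Defa35 also by limma-voom. The adjusted p-values ran from 1.48e-05 to 0.147 for Trpc2 and from 8.84e-10 to 0.247 for Defa35 over the alternatives.

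Further genes with separated groups did not pass by edgeR, although DESeq2 called each of those named next except Rsc1a1 (DESeq2 adjusted p = 0.0635). The smallest p-values among those higher belonged, after Trpc2, to Ankle1, an endonuclease gene (log2 1.34 ± 0.23, adjusted p = 0.0680), and Rsc1a1 (log2 3.64 ± 0.66, adjusted p = 0.0874). Rsc1a1 lies within Ddi2, so its reads are uncertain. Next came Vstm5 (log2 0.70 ± 0.15, adjusted p = 0.119) and Mt1, a metallothionein (log2 1.38 ± 0.30; 302.3 ± 128 against 786.3 ± 177 CPM; adjusted p = 0.121). Among those lower were the alpha-defensins Defa34 and Defa41 (log2 -1.72 ± 0.25 and -1.66 ± 0.25), C1qtnf1, a secreted protein (log2 -1.52 ± 0.23), and Smim38 (log2 -1.33 ± 0.21), each with an adjusted p of 0.0680. At an adjusted p under 0.1, 3 genes were higher and 72 lower. An unadjusted p under 0.05 was found for 1776 genes, 529 higher and 1247 lower, against 647 that independent genes would give by chance. Other splits of the same 6 libraries came close, with 1619 genes for floxed controls 1 and 3 and knockout 2 against the rest, 1538 for floxed control 1 and knockouts 2 and 3, and 1330 for floxed controls 1 and 3 and knockout 1. The groups did not overlap for 905 higher and 1339 lower genes, 17.3% of those tested where chance gives 10%.

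DESeq2 called 342 genes, 38 higher and 304 lower, and 81 of the lower ones belonged to the fixed lists. By contrast, limma-voom called 1 higher and 0 lower, with 1633 genes at an unadjusted p under 0.05. The count turned on floxed control 2: without it edgeR called 188 genes higher and 767 lower, and 325 of these 955 were among the DESeq2 calls. With floxed control 2 in place and floxed controls 1 and 3 left out, 3 genes were higher and 9 lower. The first principal component held 46.2% of the variance. On it floxed controls 1 and 3 stood at -41.3 and -37.6, while floxed control 2 stood at 11.5 beside the knockouts at 15.5, 20.2 and 31.7. Floxed controls 1 and 3 also had the smallest total counts, so library depth split the libraries in the same way.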

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

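The alternatives named for thinning, for the clock-gene split and for leaving out floxed controls 1 and 3 were chosen after the results were seen; the others were planned. Against 1 gene higher and 1 lower, both past 2-fold, RLE scaling gave 0 and 0, and TMM without the 50 most abundant genes gave 0 and 0, as the adjusted p passed 0.05 while the fold changes held. DESeq2 gave 38 and 304 (past 2-fold 8 and 226), limma-voom 1 and 0, and no filter 3 and 64 (past 2-fold 3 and 63). With a replicate block the counts were 3 and 36, at 2-fold too; same-numbered libraries had residual correlations of -0.177, -0.272 and 0.068, so the numbers were not taken to pair the libraries, and not every library correlated best with its own number. The block also brought the enterocyte list past the threshold and ended no list's call. Leaving out each library gave 0 to 188 genes higher and 0 to 767 lower, and 0 to 28 and 0 to 609 past 2-fold. The clock-gene split as a term gave 0 higher and 1 lower, which was not Defa35, and also called the enterocyte list lower. Without the 2 libraries of the clock-gene split there were 185 higher and 735 lower, and 58 and 638 past 2-fold. Without floxed controls 1 and 3 there were 3 and 9, at 2-fold too; the lone control was assumed to vary like the knockouts. The cause of these shifts was not tested. The 3 higher and 10 lower lists became 0 and 0 with an estimated correlation and with fry (lowest adjusted p 0.152), and all 13 were called again under RLE scaling. Without floxed controls 1 and 3, 1 list (interferon) was higher and 7 lower, and 6 of the 13 were among them. In that setting the log2 change turned sign for Alpi (0.35), Nkg7 (0.14), Pou2af1 (0.088), Ms4a1 (0.28), Slc5a1 (0.076), Duoxa2 (-0.18), Itgax (0.53), Fcer1g (1.08) and Tyrobp (0.80), and the median for the S phase (-0.034), T cell (0.18), B cell (0.19), enterocyte (0.35), myeloid (0.15) and antimicrobial (-0.043) lists. Over single libraries left out, Alpi ranged from -0.38 to 0.10, Il18 from -0.20 to 0.55 and the enterocyte median from -0.36 to 0.051. The endothelial call was also lost under the CPM filter (median -0.50) and thinning (-0.49), the Notch call under the CPM filter (-0.30) and without genes of more than 1 list (-0.27), and the interferon call without the 2 libraries of the clock-gene split (0.14). The median log2 fold change of all genes stayed between -0.0227 and 0.0231. The planned Fpr2 fold change and its alternatives were not run, as Fpr2 was not analysed here. At this depth genes near the floor, such as Trpc2 in the floxed controls, rest on few counts.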

Other observations

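Clock genes, looked at after the results were seen, followed neither group. Dbp stood at 6.81 CPM in floxed control 2 and 4.43 CPM in knockout 1, against 24.9, 44.2, 23.8 and 25.7 CPM in floxed controls 1 and 3 and knockouts 2 and 3. Arntl, in the opposite phase of the daily cycle, stood at 27.8 and 34 CPM in that pair and at 12, 7.48, 11.4 and 5.93 CPM in the other 4. Per3 was at 5.97 and 6.15 CPM in the pair, against 29.1, 22.6, 28.7 and 33.9 CPM.

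The tests that follow were chosen after the results were seen, except the count over other splits of the libraries. There are 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05. The real split called 2 genes and the highest other split 0, so the real split was the 1 of the 10 splits with as many. At 2-fold these counts were also 2 and 0, again with 1 split of 10. It called 13 lists, 5 of the 10 splits gave as many, and the highest other split, floxed controls 1 and 3 with knockout 3 against the rest, called 18.

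The lower Paneth list was set against 3 technical explanations. Reads shared among alpha-defensin copies would leave the family's sum level, but the summed CPM differed by -1.76 on the log2 scale, with each knockout below each floxed control. For a difference in library depth, the median was -1.69 after every library was thinned to the smallest total. Random thinning leaves the expected ratios of abundant genes unchanged, so that value cannot decide. Floxed control 2, with 16695304 counts, was about as deep as the knockouts. Its share of counts in the Paneth list was 9.20%, against at most 5.36% in the knockouts, but it is 1 library. Collection time, as read from clock genes, is argued against by a list difference of -1.85 between knockouts 2 and 3 and floxed controls 1 and 3. The difference of -0.94 between knockout 1 and floxed control 2 sets 1 library against 1, without a measure of spread. Floxed controls 1 and 3, alike in genotype and clock genes, stood at 0.49 and 1.32, so that difference cannot decide. A smaller Paneth cell share in knockout crypts may be a candidate explanation, as a hypothesis from the same data that was not tested. These values cannot tell fewer Paneth cells from less transcript per cell. Unequal recovery of crypt bases during isolation stays open and was not tested.

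For the lower lymphocyte lists, floxed controls 1 and 3 alone may have carried more lymphocytes. Floxed control 2 differed from the knockout mean by -0.14 on the T cell list and -0.38 on the B cell list, while floxed controls 1 and 3 stood at least 1.51 above that mean on the T cell list. Collection time is argued against, because knockouts 2 and 3, with the clock gene levels of floxed controls 1 and 3, differed from them by -1.58 on the T cell list. All 13 genes of the T cell list are of blood cells, and its most abundant members, Gzma and Ccl5, stood at 85.4 and 56 CPM in floxed control 1. An effect of genotype on lymphocytes, with floxed control 2 as the exception, stays open and untested.

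The rise of Trpc2 may come from reads moved between Trpc2 and Xntrpc, whose span contains it. The summed CPM of both differed by 0.29 on the log2 scale, with overlapping groups, and Xntrpc was lower in each knockout than in each floxed control. For Rsc1a1 and Ddi2 the summed CPM differed by -0.052, but Ddi2 (55.0 ± 6.58 against 44.6 ± 11.8 CPM; SD, n = 3) overlapped between the groups, so reads moved from Ddi2 and a rise of Rsc1a1 cannot be told apart. Fam177a2 had 0 counts in the floxed controls and 4.15, 4.27 and 26.4 CPM in the knockouts, while its summed CPM with its copy Fam177a differed by -0.075, in line with reads moved between the copies. A difference in strain background at these loci is a further open explanation, not tested.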
